A study of Homo sapiens with 2 samples.

How the data were processed

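RNA sequencing libraries were analysed from HBEC-3KT cells, 2 in all, 1 from cells transduced with a lentivirus carrying human CBS and 1 from cells given the empty vector. Per the labels' protocols, cells were exposed to virus for 4 to 8 hours, selected with blasticidin at 10 µg/mL and kept for 4 to 5 days on gelatin-coated plates. RNA was sequenced on the DNBseq platform. Groups were taken from the genotype given in the labels. Each group held 1 library, so the spread between cultures is unknown. Trimmomatic 0.39, STAR 2.6.1d, RSEM 1.3.2 and the GRCh38 assembly are named in the submitters' processing notes, without their roles or order. The annotation release, strandedness and read layout were not given in the sources used here.

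The authors deposited expected counts per gene, estimates that need not be whole, and 15.5% and 15.8% of genes held a value that was not whole in the CBS and empty-vector libraries. The authors also deposited TPM values, transcript levels scaled for length and depth, whose sum is the same in each library. The expected counts were rounded to whole numbers before use. They summed to 20785957 in the CBS library and 20433062 in the empty-vector library. At least 10 counts were reached by 14554 and 14935 genes. TPM served only as an alternative, as log2(TPM + 1).

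The table held 60619 genes, 35259 of them with a symbol. Symbols that a spreadsheet had turned into dates, 27 in all, were replaced by the symbol of the gene ID in a table of gene names. Genes with at least 10 counts in at least 1 library and a mean of at least 1 CPM were kept, which left 13304. TMM factors were computed with edgeR 4.0.16 in R 4.3.3, with no model fitted, and were 1.03 for the CBS library and 0.975 for the empty vector. Size factors from DESeq2 1.42.0 served as an alternative, again with no model fitted. Log2 folds are CBS over empty vector with a prior count of 5 scaled to library size. Each fold has an exact 95% interval (Clopper-Pearson, conditional binomial) made without the prior count. These intervals cover counting error only. They may be too narrow even for that, since PCR-amplified reads are not independent molecules and the expected counts are estimates. A gene was counted as higher or lower when its fold reached 2 and its interval excluded a ratio of 1. These counts compare the 2 libraries, not the conditions.

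Before the data were examined, 39 gene lists were written from general knowledge, and 36 of them had at least 3 kept members. The median log2 fold of each was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. Lists with fewer members are given as summed CPM. The genes named were set by a rule fixed at the same time. It takes CBS and CBSL, EZH2, EED and SUZ12, the 15 highest and 15 lowest log2 folds among genes with a symbol, at least 100 counts in 1 library and an interval that excludes a ratio of 1, and in each list up to 4 members with the largest absolute log2 fold and at least 100 counts. Some genes the rule takes are not reported here. The rule asked for protein-coding genes where the files mark them, which they do not. Another 5 lists were written after the data were seen and are used only in the closing observations.

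The calculation of folds, intervals and percentiles was tested on simulated data. Poisson counts were drawn for the comparison of CBS with empty vector, with 13304 genes analysed and 200 of them given known folds. Intervals held the true fold for 95.4% of unchanged genes, and 0.02% of these were called. For the changed genes, 50 per fold, intervals held it in 92.0% to 100.0% of cases. Genes with a true log2 fold of 1 or -1 were called in 40.0% of cases and those with 2 or -2 in 100.00%. Random lists of 25 genes fell outside the central 95% in 2.0% of 100 draws, and lists shifted by 0.5 in 99.0%. For these draws, normal noise with a standard deviation of 0.5 was added to each log2 fold, independently for each gene. Lists whose genes vary together were not simulated. Variation between cultures was not simulated either, so the share of unchanged genes called says nothing about false calls between real cultures. Simulated counts were scaled by plain library totals, so TMM scaling was not tested.

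GC content and length came from the longest transcript of each gene in GENCODE 29, matched by gene ID for 93.9% of the IDs and 99.4% of the kept genes. Their trend was removed by lowess with a span of 0.3 (statsmodels 0.14.6), an alternative chosen after seeing the data. Intervals were not recomputed for it. The alternatives set before the data were examined were DESeq2 size factors, plain library totals, the authors' TPM, prior counts of 1 and 20, no filter on low counts, a filter of 100 counts, fold thresholds of 1.5 and 4, protein-coding genes only, and the sum of CBS and CBSL. Coordinates are those of the deposited table. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.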

Results

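Gene expression was measured by RNA sequencing of total RNA from HBEC-3KT, an immortalized cell line of human bronchial epithelium that grows as basal-like cells. Cells had been transduced with a lentivirus carrying human CBS or with the empty pLenti6 vector. CBS encodes cystathionine beta-synthase, the enzyme that condenses homocysteine with serine in the first step of transsulfuration. The question set by the design was how CBS expression bears on the function of Polycomb repressive complex 2 (PRC2), a methyltransferase complex that marks histones at silenced genes. Each group held 1 library, with 20785957 estimated counts for CBS overexpression and 20433062 for the empty vector. No difference reported here has a replicate check, and no test between the conditions was possible. The intervals given are exact 95% intervals for the ratio of the counts of 2 libraries and cover counting error only. Folds are CBS over empty vector after TMM scaling, and log2 folds carry a prior count of 5.

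CBS was among the genes furthest apart, which matches the labels of both libraries. The gene (ENSG00000160200, GRCh38 chromosome 21, 43053191 to 43076943) had 3669 counts in the CBS library and 280 in the empty-vector library. That is 172 against 14.1 CPM (counts scaled to library size), a 12.2-fold higher level (95% counting interval 10.8 to 13.9). CBSL (ENSG00000274276, chromosome 21, 6444869 to 6468040), a near-identical copy of CBS in this assembly, had 4378 against 343 counts and was 11.9-fold higher (10.7 to 13.3). Reads of a CBS transcript cannot be assigned to one copy with certainty, so the split between them is uncertain. Their sum of 8047 against 623 counts was 12.1-fold higher (11.1 to 13.1). In the authors' TPM the fold was 8.90 for CBS, 14.3 for CBSL and 11.4 for the sum. The files do not separate transcripts of the vector from those of the cells' own gene.

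Transcripts of the 3 genes of the PRC2 core had log2 folds from 0.11 to 0.55. EZH2 (chromosome 7, 148807383 to 148884321), the catalytic subunit, had 777 counts with CBS and 624 with the empty vector, a log2 fold of 0.22 (0.06 to 0.37). EED (chromosome 11, 86244544 to 86278813), the subunit that binds methylated histone H3, had 412 against 261 counts and a log2 fold of 0.55 (0.33 to 0.79). SUZ12 (chromosome 17, 31937018 to 32001045), which holds the complex together, had 1086 against 937 counts, and its log2 fold of 0.11 had an interval that held no difference (-0.01 to 0.24). Across the 15 measured genes of the PRC2 list, which also holds the opposing demethylases, the median log2 fold was 0.10, at percentile 69.98 of 10000 random lists of the same size and expression. An interval that excluded a ratio of 1 was common, at 62.7% of all 13304 genes above the filter. Of the 15 genes of the PRC2 list, 6 had an interval above a ratio of 1, 4 had one below and 5 had one that held 1. The member furthest from a ratio of 1 was KDM6B, a demethylase that removes the PRC2 mark, with 779 against 1485 counts and a log2 fold of -1.02 (-1.16 to -0.90). PHF1 at -0.52 (-0.71 to -0.35) and JARID2 at -0.39 (-0.49 to -0.29), both accessory subunits, were also lower. The list of PRC1 subunits, the companion complex, had a median of 0.06 at percentile 64.16 over 20 genes. Members with at least 100 counts included CBX7 at -0.61 (-0.97 to -0.29), RING1 at -0.46 (-0.58 to -0.33) and PCGF6 at 0.42 (0.15 to 0.71). Of the PRC1 list, 1 member, with fewer counts, was at least 2-fold higher, and none was at least 2-fold lower. After removal of the trend on GC content and length, the PRC2 median was 0.00 at percentile 35.23, with EZH2 at 0.11, SUZ12 at 0.00, EED at 0.45, PHF1 at -0.35 and KDM6B at -0.78, and the PRC1 median was -0.02.

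**Figure D1:**
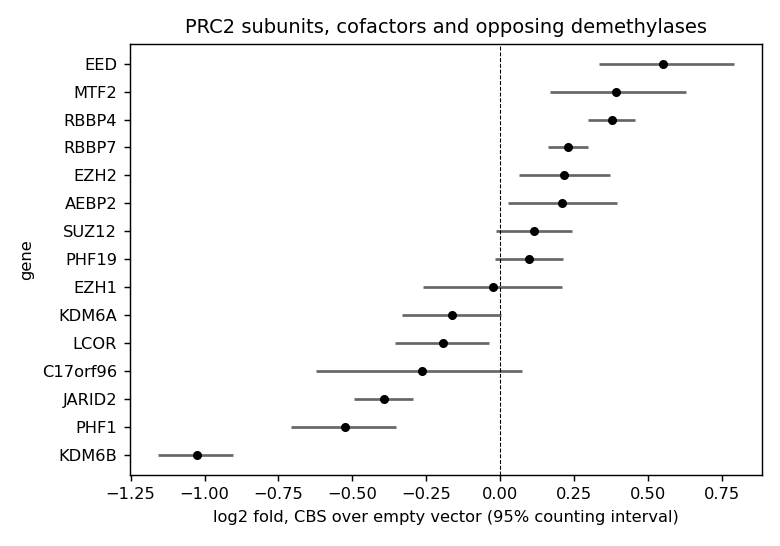
Log2 fold of the 15 measured genes of the PRC2 list, CBS over empty vector, with 1 library per group. Points are folds, and horizontal lines are exact 95% counting intervals of the ratio. KDM6B lies lowest at -1.02 and EED highest at 0.55.

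Developmental regulators that PRC2 keeps silent in many cell types showed no common direction. Of 112 such genes, 41 were expressed above the filter, with a median log2 fold of 0.02 at percentile 56.08. The interval lay above a ratio of 1 for 13 genes, below it for 16 and held it for 12. The median was -0.00 without the filter, -0.04 over members with at least 100 counts, and 0.14 at percentile 96.95 with the trend on GC content and length removed. ISL1, a homeobox factor, was at least 2-fold higher, with 101 against 40 counts and a log2 fold of 1.15 (0.70 to 1.80). Lower members were BMP2, a signalling ligand, at -1.86 (-2.16 to -1.64), BARX2, a homeobox factor, at -1.42 (-1.70 to -1.20) and FOXC1, a forkhead factor, at -1.04 (-1.14 to -0.94). HOX genes had a median of 0.12 at percentile 88.41 over 10 measured genes, and the interval of each of the 10 held a ratio of 1, as for HOXC9 at 0.27 (-0.15 to 0.72) and HOXA5 at 0.14 (-0.18 to 0.47). Of the 151 genes of these 2 lists, 100 lay below the filter and 60 had no count in either library. In the empty-vector library 89 had at most 3 counts, and none of these 89 reached 20 counts in the CBS library, where the highest had 13. HOXB9, singled out after its values were seen, had 3 counts with CBS and 24 with the empty vector. Switching on of a silent regulator above the level of 20 counts was thus not detected at this depth. Stronger silencing could not show in the 60 genes without a count in either library. It could hardly show in any of the 89 genes, these 60 among them, with at most 3 counts in the empty-vector library. The 100 genes below the filter summed to 163 counts in that library. The activity of PRC2 and its histone mark were not measured, so these transcript levels do not show whether either changed.

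DNA and histone methyltransferases and demethylases had a median log2 fold of 0.21 over 35 genes, at percentile 99.23. UHRF1 was at 0.92 (0.82 to 1.02) and DNMT1 at 0.71 (0.64 to 0.78), both of which act in maintenance DNA methylation. The de novo DNA methyltransferases DNMT3B and DNMT3A were at 0.66 (0.30 to 1.09) and -1.09 (-1.43 to -0.82). This list lay inside the central 95% of random lists with the authors' TPM (percentile 93.99) and with the trend on GC content and length removed (97.33).

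Over all 13304 genes above the filter, 188 were at least 2-fold higher in the CBS library and 703 were at least 2-fold lower, counting only genes whose interval excluded a ratio of 1. Lower genes made up 78.9% of these. PRR5-ARHGAP8, a readthrough of neighbouring genes that shares reads with both, had the highest log2 fold of the well-counted genes at 4.29 (3.95 to 6.35), with 243 against 7 counts. After it came CBS and CBSL, then VGLL1, a cofactor of TEAD transcription factors, at 2.93 (2.51 to 4.65). DKK1, a secreted Wnt antagonist on chromosome 10 (52314296 to 52318042), had 1656 against 250 counts and a log2 fold of 2.61 (2.44 to 2.83). FST, which encodes the activin antagonist follistatin, on chromosome 5 (53480409 to 53487134), had 3157 against 577 counts and a log2 fold of 2.34 (2.23 to 2.48). The other genes of the highest 15 were SYT16 at 2.45, TGIF2-C20orf24, another readthrough, at 2.45, ITGBL1 at 2.40, SLC8A1 at 2.21, GTF2H2B at 2.09, CD3EAP, a subunit of RNA polymerase I, at 1.98, MARCHF4 at 1.93, CYP2U1 at 1.83 and the arginine transporter SLC7A2 at 1.70. The values of both readthroughs and of GTF2H2B, a copy of GTF2H2, are uncertain because they share sequence with other genes.

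At the low end, NOTCH3, a Notch receptor on chromosome 19 (15159038 to 15200981), had 27 counts with CBS and 854 with the empty vector, a log2 fold of -4.84 (-5.69 to -4.53). CDH6, a cadherin, followed at -4.78 (-6.10 to -4.46). GJB2, which encodes the gap junction protein connexin 26, on chromosome 13 (20187470 to 20192898), had 191 against 3942 counts and a log2 fold of -4.43 (-4.68 to -4.26). IL33, an epithelial alarmin, was at -3.81 (-4.40 to -3.52), and CA9, a hypoxia-induced carbonic anhydrase, was at -3.48 (-3.69 to -3.33) with 281 against 2979 counts. The rest of the lowest 15 were SERPINB3 at -3.69, C10orf10 at -3.63, DHRS9 at -3.34, SERPINB4 at -3.10, WNT9A at -2.98, ICAM5 at -2.90, MMP28 at -2.88, CHAC1 at -2.85, KCTD11 at -2.84 and LCP1 at -2.82. SERPINB3 and SERPINB4 are near-identical copies, so the split of reads between them is uncertain. On log2(TPM + 1), which compresses the folds of low genes, the log2 fold of NOTCH3 was -2.69 and the log2 fold of SYT16 was 0.53. The 2-fold counts depended on the measure, with 377 genes lower in the authors' TPM and 121 genes higher at a prior count of 20. Genes in TPM were called on the fold alone, with no interval required. Log2 folds also followed transcript GC content across genes (Spearman correlation -0.28 over 13225 genes, which are not independent replicates), with a median of 0.12 in the fifth of genes with the lowest GC content and -0.23 in the fifth with the highest. With this trend removed, 190 genes were higher and 614 lower.

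**Figure D2:**
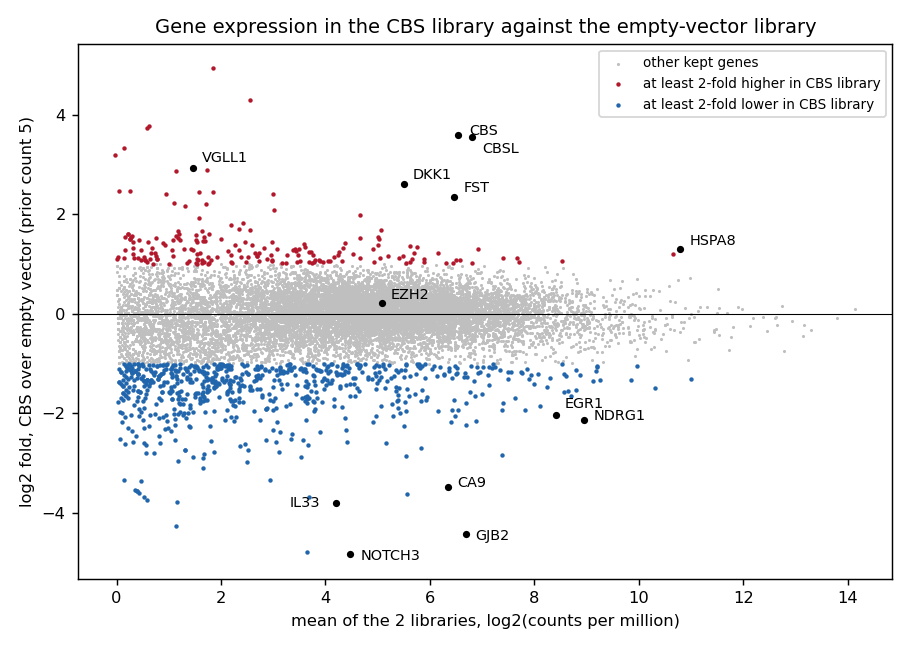
Log2 fold of 13304 genes, CBS over empty vector, against the mean CPM of both libraries on a log2 scale, with 1 library per group. Red points are the 188 genes at least 2-fold higher and blue points the 703 at least 2-fold lower whose counting interval excluded a ratio of 1. CBS and CBSL lie at 3.59 and 3.56, and NOTCH3 at -4.84.

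Around CBS in metabolism, genes of the methionine cycle had a median log2 fold of 0.17 over 18 genes, at percentile 93.86. With the trend on GC content and length removed, that median was 0.10 at percentile 79.97. SHMT1, a folate enzyme, was at 0.96 (0.86 to 1.07) and ENOPH1, of methionine salvage, at 0.85 (0.72 to 0.98), while NNMT, which consumes S-adenosylmethionine, was at -1.48 (-1.99 to -1.13). Transsulfuration and hydrogen sulfide genes other than CBS had a median of 0.09 at percentile 70.96 over 12 genes, with SUOX at 0.61 (0.38 to 0.86) and TST at -0.32 (-0.53 to -0.12), or -0.07 with the GC trend removed. Glutathione genes had a median of -0.16 at percentile 4.92 over 22 genes, or 0.02 at percentile 18.82 in the authors' TPM. Lower members were CHAC1, which degrades glutathione, at -2.85 (-3.08 to -2.68) and GSTM3, a glutathione transferase, at -1.32 (-1.85 to -0.96). NRF2 targets had a median of 0.16 at percentile 95.82 over 25 genes, with OSGIN1 at 1.22 (0.89 to 1.67), TXNRD1 at 1.03 (0.94 to 1.12) and ABCC3 at -1.12 (-1.40 to -0.90). The 12 measured chromosome 21 neighbours of CBS had a median of 0.21 at percentile 93.35, with WDR4 at 0.60 (0.35 to 0.88). Cholesterol synthesis genes had a median of 0.04 at percentile 70.89 over 24 genes, with HMGCS1 at 0.64 (0.60 to 0.69) and STARD4 at -0.61 (-0.70 to -0.52).

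Hypoxia and glycolysis genes were lower as a group in the CBS library. Of 30 genes, 29 had an interval below a ratio of 1 and 10 were at least 2-fold lower, with a median log2 fold of -0.49 at percentile 0.00. Besides CA9, NDRG1, a hypoxia-induced gene, was at -2.13 (-2.18 to -2.08) with 3927 against 16084 counts, the neuronal enolase ENO2 at -1.90 (-2.08 to -1.75) and the glucose transporter SLC2A3 at -1.65 (-1.99 to -1.40). Amino acid stress genes controlled by ATF4 had a median of -0.28 at percentile 0.05 over 34 genes, 23 of them with an interval below a ratio of 1 and 6 above. Among them were CHAC1, DDIT3, the stress factor CHOP, at -2.38 (-2.76 to -2.12), SESN2, a sestrin, at -1.75 (-1.90 to -1.62) and STC2, a secreted stanniocalcin, at -1.65 (-1.70 to -1.60). Immediate early genes had a median of -0.60 at percentile 0.00, with 23 of 29 intervals below a ratio of 1. FOS was at -2.70 (-2.90 to -2.55), EGR1 at -2.04 (-2.10 to -1.98), KLF4 at -1.70 (-2.04 to -1.44) and DUSP1 at -1.66 (-1.82 to -1.52). Targets of p53 had a median of -0.37 at percentile 0.00 over 28 genes, 17 with an interval below and 6 above a ratio of 1, including GDF15 at -1.06 (-1.15 to -0.98) and BBC3 at -1.05 (-1.48 to -0.72).

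Inflammatory and NF-kB genes had a median log2 fold of -0.71 at percentile 0.00, and 19 of 26 had an interval below a ratio of 1. Besides IL33, LCN2, a secreted siderophore binder, was at -1.92 (-2.05 to -1.82), the epithelial cytokine TSLP at -1.90 (-2.42 to -1.58) and TNFAIP3, an NF-kB feedback inhibitor, at -1.75 (-1.93 to -1.60). Immune cell markers summed to 40.1 CPM with CBS and 125.3 with the empty vector, a difference that rested on CD68, a lysosomal protein of macrophages and other cells, with 619 against 2259 counts. CD14, the other measured marker, was at 0.05 (-0.23 to 0.33). Interferon-stimulated genes had a median of 0.15 at percentile 96.26 over 32 genes, with IFIT3 at 0.92 (0.61 to 1.29) and SAMD9 at -1.50 (-1.66 to -1.36). Their percentile was 99.05 in the authors' TPM and 99.09 without the filter, but 90.28 with the GC trend removed and 70.57 over members with at least 100 counts. MHC class I presentation genes had a median of 0.13 at percentile 87.23 over 16 genes. Within them the heavy chains HLA-B at -0.85 (-0.93 to -0.77) and HLA-C at -0.81 (-0.87 to -0.75) were lower, and NLRC5, a transactivator of the pathway, was at 1.51 (1.09 to 2.17). The HLA genes resemble each other, so reads may be split between them. MHC class II genes had a median of -0.64 at percentile 11.52 over 3 genes, with HLA-DQB1 at -0.95 (-1.33 to -0.63).

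Squamous differentiation genes had one of the lowest medians, -1.15 at percentile 0.00, with 19 of 22 intervals below a ratio of 1 and 11 genes at least 2-fold lower. Besides the SERPINB genes, TGM1, a transglutaminase of the cornified envelope, was at -2.67 (-3.54 to -2.29) and the keratin KRT6B at -2.17 (-2.30 to -2.05). Basal cell markers had a median of -0.41 at percentile 0.10 over 18 genes, 12 with an interval below a ratio of 1 and 3 above. The keratins KRT14 at -2.15 (-2.26 to -2.06), KRT15 at -1.94 (-2.03 to -1.86) and KRT17 at -1.49 (-1.52 to -1.46) were lower, as was the laminin chain LAMB3 at -1.31 (-1.33 to -1.28). Keratins have close paralogs, which limits how exactly their reads can be assigned. Mesenchymal genes had a median of -0.48 at percentile 0.00 over 22 genes, with the integrin ITGA5 at -1.78 (-1.87 to -1.71) and fibronectin, FN1, at -1.32 (-1.36 to -1.29). Matrix proteases and their inhibitors had a median of -0.49 at percentile 0.01 over 21 genes, with TIMP1 at -1.57 (-1.62 to -1.52) and, higher, ADAMTS1 at 1.51 (1.34 to 1.70). Fibroblast markers summed to 8.77 CPM with CBS and 15.9 with the empty vector, COL1A1 being at -1.10 (-1.44 to -0.82), and endothelial markers to 10.9 and 10.3 CPM, EGFL7 being at -0.54 (-0.91 to -0.20) and CDH5, named after its values were seen, at 2.86 (2.43 to 4.89) with 87 against 7 counts.

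Among other airway cell states, alveolar markers had a median of 0.68 at percentile 99.87 over 5 genes. PDPN was at 1.01 (0.73 to 1.36), LAMP3 at 0.80 (0.52 to 1.12), caveolin CAV1 at 0.68 (0.65 to 0.72) and AGER at -0.75 (-1.21 to -0.37). The other 11 members of the list lay below the filter, and without the filter the median was 0.16 at percentile 92.07. PDPN is also on the basal list. Neuroendocrine markers had a median of -1.53 at percentile 0.90 over 3 genes, one of which is ENO2. Secretory markers had a median of -0.26 at percentile 9.16 over 4 genes, with the protease inhibitor SLPI at -2.54 (-3.02 to -2.26) and AGR2, a disulfide isomerase, at 1.22 (1.11 to 1.34). Ciliated markers had a median of -0.01 at percentile 62.35 over 8 genes, with DNAH11 at -1.62 (-1.99 to -1.35). Their median was 0.05 with plain library totals (percentile 61.73) and in the authors' TPM (percentile 60.08). Epithelial junction genes had a median of -0.16 at percentile 7.42 over 23 genes, and 2.14 without the filter. ELF3 at -1.23 (-1.47 to -1.03) and JUP at -0.71 (-0.74 to -0.68) were lower, and the keratin KRT18 was higher at 0.68 (0.66 to 0.70).

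Proliferation genes were higher in the CBS library, with a median log2 fold of 0.30 at percentile 100. The interval lay above a ratio of 1 for 37 of 44 genes and held it for 7. CDC25A, a phosphatase that drives entry into S phase, was at 1.38 (1.22 to 1.57), cyclin E2, CCNE2, at 1.07 (0.76 to 1.46), and the replicative helicase subunits MCM2 at 0.96 (0.88 to 1.05) and MCM6 at 0.96 (0.87 to 1.06). Heat shock genes had a median of 0.57 at percentile 100, with 13 of 15 intervals above a ratio of 1. HSPA8 had 54079 against 20373 counts and a log2 fold of 1.31 (1.29 to 1.33), HSP90AA1 was at 1.20 (1.18 to 1.23) and HSPE1 at 0.95 (0.83 to 1.08), while the small heat shock protein HSPB1 was at -1.56 (-1.61 to -1.51). Unfolded protein response genes had a median of 0.23 at percentile 99.16 over 21 genes, which was 95.06 in the authors' TPM and 94.46 with the GC trend removed. HSP90B1 was at 0.71 (0.68 to 0.73), and HERPUD1 at -0.99 (-1.15 to -0.84) and XBP1 at -0.69 (-0.78 to -0.62) were lower. Nuclear genes of oxidative phosphorylation had a median of 0.17 at percentile 97.73 over 39 genes, with NDUFV2 at 0.66 (0.56 to 0.76) and CYCS at 0.59 (0.52 to 0.66).

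Among the remaining lists, transcripts encoded in the mitochondrial genome had a median of -0.14 at percentile 33.89 over 13 genes, with MT-ND3 at -0.40 (-0.42 to -0.37) and MT-CO2 at -0.32 (-0.33 to -0.31). Mitochondrial ribosomal RNA took 0.62% of the counts with CBS and 0.96% with the empty vector. Cytosolic ribosomal protein genes had a median of -0.17 at percentile 9.88 over 56 genes, 44 of them with an interval below a ratio of 1, with RPS19 at -0.67 (-0.71 to -0.63). Their percentile was 1.53 with the GC trend removed. Metallothioneins had a median of -0.09 at percentile 38.04 over 6 genes, with MT1X at -1.93 (-2.01 to -1.86) and MT1E at 0.36 (0.31 to 0.40). Their median was 0.01 at percentile 37.91 in the authors' TPM and 0.17 at percentile 82.07 over members with at least 100 counts. Replication-dependent histone genes had a median of 0.02 at percentile 77.33 over 7 genes, with HIST1H2BK at 1.38 (0.99 to 1.95). The histone median was -0.00 without the filter and 0.22 at percentile 91.95 with the GC trend removed. In all, 10 of the 36 lists with at least 3 measured genes had a median below the central 95% of random lists and 6 had one above it. Separate lists of genes that vary independently would give 1.8 outside. Genes of a list can vary together and some lists share members, so that number is no firm reference. These percentiles describe the 2 libraries and do not test the conditions.

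**Figure D3:**
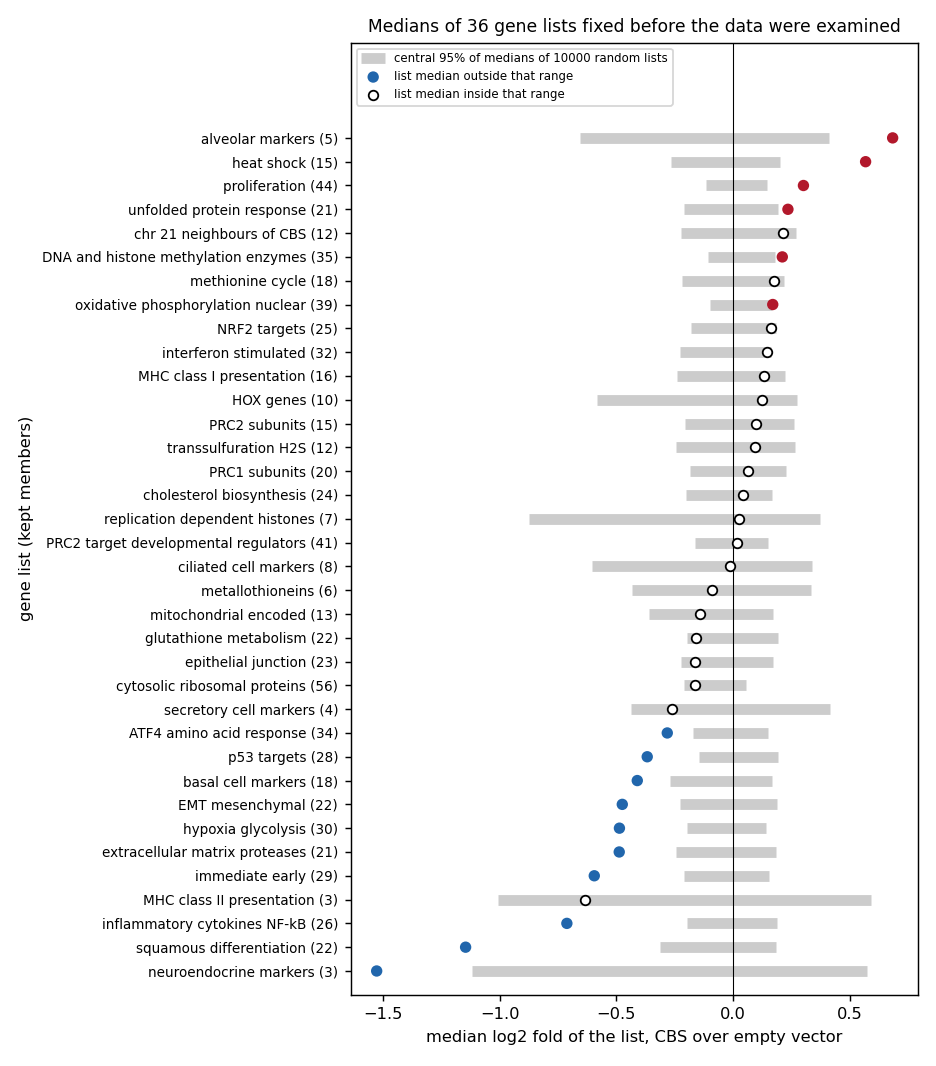
Median log2 fold of 36 gene lists, CBS over empty vector, with the number of measured genes in parentheses. Grey bars span the central 95% of the medians of 10000 random lists of matched size and expression, filled points lie outside that range and open points inside. The squamous list lies at -1.15 and the heat shock list at 0.57.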

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

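The alternatives were planned before the data were examined, except removal of the GC and length trend and a prior count of 5 for the CBS fold. No paired analysis was possible because each group held 1 library, and for the same reason no library could be left out. The CBS fold was 8.34 with the authors' TPM + 1 and lay inside its counting interval under the other alternatives run. In the authors' TPM, where genes were called on the fold alone with no interval required, 377 genes were at least 2-fold lower. A prior count of 20 left 121 genes at least 2-fold higher. Without the filter on low counts 431 genes were higher and 1281 lower, and with at least 100 counts 115 and 438, since the filter sets how many genes enter. A threshold of 1.5 gave 934 and 1712 genes and one of 4 gave 23 and 105, as the threshold itself requires. The cause of the moves with TPM was not tested. Lower genes outnumbered higher ones under each scaling, from 70.5% of the called genes in the authors' TPM to 79.0% with DESeq2 size factors. Of 161 named genes, none with an interval that excluded a ratio of 1 reversed its direction under the alternatives of scaling, prior count or GC correction. Their size was less stable, and folds left the counting interval for 91 genes with the authors' TPM, 52 with GC correction, 32 with plain library totals and 15 with a prior count of 20. Of the 16 lists outside the central 95% of random lists, none changed direction, while the medians of 6 lists inside it (glutathione, PRC1, PRC2 target, ciliated, metallothionein and histone genes) changed sign under at least 1 alternative. The median over all genes moved too, from 0.00 to 0.09 in the authors' TPM and 0.07 with plain library totals. A change of sign under either can thus reflect that shift, whereas percentiles are taken within each scaling. With DESeq2 size factors, plain library totals and other prior counts, no list crossed the edge of the central 95%. The lists that crossed it did so with the authors' TPM (3 lists), without the filter (3) and with the GC trend removed (3). With at least 100 counts, 33 lists had enough members, and none crossed. The PRC2 subunit, PRC2 target and HOX lists stayed inside under each alternative that gave them a value. Depth limits genes with few counts, and one library per group limits everything else.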

Other observations

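The lists used in this part, the tests of cell dilution and the removal of the GC trend were chosen only after the results were seen. Ribosome biogenesis genes were higher in the CBS library, with 34 of 35 intervals above a ratio of 1 and a median log2 fold of 0.59. UTP20, a processome component, had 914 against 343 counts and UTP15 had 993 against 462, RRP12 was at 0.87 (0.75 to 0.99) and RRS1 at 0.85 (0.70 to 1.01), while genes of the ribosomal proteins themselves were not higher as a group. S-phase genes had a median of 0.71, with 41 of 43 intervals above a ratio of 1, among them CDCA7 at 1.22 (1.09 to 1.36), TIPIN at 1.03 (0.80 to 1.32) and DTL at 0.98 (0.87 to 1.10). G2/M genes had a median of 0.18 at percentile 99.60 over 52 genes, or 0.14 at percentile 96.84 with the GC and length trend removed, led by LBR at 0.56 (0.44 to 0.68) and HMGB2 at 0.54 (0.45 to 0.63), so the S-phase median was higher by 0.53.

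Targets of YAP and TAZ, transcriptional cofactors that respond to cell density and tension, had a median of 0.35, with 15 of 22 intervals above a ratio of 1 and 4 below. TGFB2 at 1.19 (0.98 to 1.44), NT5E at 0.73 (0.67 to 0.79) and MYOF at 0.69 (0.65 to 0.73) were higher, and IGFBP3 at -2.23 (-2.36 to -2.13) was lower. Of genes with a symbol, 10 had at most 3 counts with the empty vector and at least 20 with CBS, including ANKRD1 with 41 against 3, and 34 showed the opposite, including STRA6 with 2 against 87. These examples were picked after their values were seen. CBS had 1.47 times as many counts per TPM in the CBS library as in the empty-vector library. For 10458 well-counted genes the median of that ratio was 0.986 and the central 95% ran from 0.814 to 1.24. For CBSL the ratio was 0.893, inside that range.

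Hypoxia, ATF4, squamous and immediate early genes were lower together in the CBS library, with a pooled median log2 fold of -0.54 and 92 of 113 intervals below a ratio of 1. GC content and length do not account for most of it, since the median was -0.49 after their trend was removed (bootstrap interval over genes -0.62 to -0.37). A large share of fibroblasts, endothelial cells or immune cells in the CBS library is argued against by their 38 markers, 6 of which passed the filter, since the median marker had 0.5, 1.5 and 0.0 counts there, although CDH5, an endothelial cadherin, had 87 counts against 7. Dilution by other cells that are not epithelial would lower all epithelial genes alike. The median of the epithelial junction genes was -0.16, with a bootstrap interval (-0.30 to 0.40) above -0.54. That bound replaced an earlier one of -0.27, which the interval reached, after the values were seen. Basal cell markers, also epithelial, had a median of -0.41 with a bootstrap interval (-0.88 to -0.04) that held -0.54. These lists therefore do not settle whether dilution contributed. A sparser culture may account for the pattern, given the YAP and TAZ targets at percentile 99.99 of random lists, and so may CBS itself, which was not tested apart from culture density because each group is 1 library.

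S-phase genes were higher in the CBS library. After the GC and length trend was removed, the median was 0.62 (bootstrap interval over genes 0.48 to 0.75). That argues against the trend as the whole cause. Such a bootstrap interval covers the spread of genes within a list, not the spread between cultures. A faster growing culture is a candidate explanation, with ribosome biogenesis at percentile 100 of random lists. Other related lists varied, with medians of 0.30 for proliferation, 0.18 for G2/M and -0.17 for cytosolic ribosomal protein genes. Growth itself was not measured, and an effect of CBS was not tested apart from a difference between cultures, with 1 library each.

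HLA class I heavy chains were lower in the CBS library, with all 5 intervals below a ratio of 1, a median of -0.81, and HLA-F at -1.15 (-1.55 to -0.84). These genes were taken out of the MHC class I list because they were seen to be low, so their place among random lists (percentile 0.20, or 0.71 after GC and length correction) is no separate evidence. The median was -0.59 after correction. For 4 of the 5 genes the corrected fold stayed below -0.41, the midpoint between 0 and the uncorrected median, and for HLA-E it did not. How much of the difference GC content accounts for therefore stays open, and it cannot be told apart from an effect of CBS for these 5 genes.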
